A study of Mus musculus with 8 samples.

How the data were processed

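The series measured sorted CD45+CD11b+ cells from the blood and the heart of 4 recipient mice by droplet single-cell RNA sequencing (10x Genomics, 3′ chemistry with feature barcoding, per the labels' protocols). The recipients carried Mx1Cre and floxed c-Myb, a combination that allows the blood-forming cells of the host to be removed, and were transplanted with bone marrow from donors that had undergone stroke or from control donors. Each group held 2 mice. Blood and heart cells of a mouse were stained with different hashtag antibodies and then pooled into a single library, per the labels, so that organ was read from the hashtag and donor group from the library. The 4 libraries stand in one matrix, and barcodes carry a suffix from 1 to 4. The suffix was matched to the sample number in the submitters' descriptions. This match is an assumption, since no file states it, and every comparison between donor groups rests on it. A consequence of pooling is that heart and blood of a mouse shared amplification and sequencing, whereas the donor groups never shared a library.

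The values deposited by the authors are UMI counts per gene or hashtag and cell barcode, with no normalization. They were produced with Cell Ranger 7.1.0 on genome build mm10, per the file headers and the submitters' processing notes. The filtered set of barcodes was used as deposited. Whether reads were subsampled to equal depth when libraries were joined is not given in the sources used here. The matrix held 11130 barcodes. Control replicate 1 had 2020 barcodes with 10067873 gene UMIs, control replicate 2 had 2723 with 12560452, stroke replicate 1 had 3303 with 15843922 and stroke replicate 2 had 3084 with 16513840. Median UMIs per barcode were 4155.5, 4095, 4005 and 4689 in that order. Of 32285 gene identifiers, 32158 were found in the GENCODE vM21 annotation, from which GRCm38 coordinates were taken. Transcripts of 2 fluorescent protein transgenes were kept out of every test and of the clustering.

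Everything from here was computed for this account. Organ was called with HTODemux of Seurat 5.3.0 at its 0.99 quantile, separately in each library. It called 954 barcodes, 8.6%, as carrying both hashtags and 101 as carrying neither. Barcodes needed at least 200 genes and at most 10% mitochondrial UMIs. Scrublet in scanpy 1.11.5 was run per library with an expected rate of 6% and its automatic threshold, and called 225 barcodes, 2.09% of those past the filter. The automatic thresholds were uneven: 0.259 and 0.155 in control replicates 1 and 2, with 38 and 164 calls, against 0.434 and 0.421 in stroke replicates 1 and 2, with 16 and 7 calls. Hashtags catch only pairs that join the organs, so pairs of cells from the same organ depended on these thresholds, which removed more barcodes from the control libraries. After both steps 9658 barcodes remained, 4911 from heart and 4747 from blood.

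Counts were scaled to the barcode's total and log-transformed. The 2000 most variable genes, 30 principal components and a graph of 20 neighbours went into Leiden clustering (leidenalg 0.10.2) at resolution 1, which gave 23 clusters over both organs. Sex-linked genes were left out of the variable genes. Clusters were named from marker lists as macrophage-like, classical or nonclassical monocyte-like, neutrophil-like, dendritic cell-like, B cell-like, NK cell-like, T cell-like, mast cell or basophil-like, endothelial-like or fibroblast-like. A name needed a mean marker z-score of at least 1, and a cluster in which an unrelated second class exceeded 1.2 stayed unnamed. These limits, and a rule that haemoglobin or platelet genes name a cluster only where they lead it, were set after the data had been seen. Unnamed clusters held 20.44% and 13.38% of heart barcodes in control replicates 1 and 2 and 13.58% and 16.25% in stroke replicates 1 and 2.

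Cells were not treated as replicates. UMI counts were summed per mouse, organ and class, and classes with at least 20 barcodes in each of the 4 mice were tested with edgeR 4.0.16 (quasi-likelihood, TMM scaling, filterByExpr, Benjamini-Hochberg threshold 0.05). Stroke was compared with control within an organ over 4 sums. Heart was compared with blood over 8 sums with the mouse as a block, because both organs came from the same animals. The interaction term of donor and organ was tested in the same 8 sums. Means ± SD are CPM over the libraries of a group, that is, counts scaled to the total of a sum after the low-count filter and TMM scaling. With 2 mice against 2, an exact two-sided permutation test cannot go below p = 0.333, and chance alone leaves the groups of 1 in 3 genes without overlap. Shares were compared by that test, and between organs by an exact sign-flip test over 4 mice, which cannot go below 0.125. Per-mouse shares have exact Clopper-Pearson 95% intervals, which cover counting error only.

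Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation and with fry, whenever at least 5 members were tested. The lists were inflammasome and interleukin-1, NF-kB and TNF response, type I interferon response, interferon gamma response, MHC class II presentation, chemokines and their receptors, matrix remodelling, resident cardiac macrophage, lysosome and lipid handling, glycolysis and HIF-1, oxidative phosphorylation, cholesterol synthesis, cell cycle, immediate early and heat shock genes, and regulators of trained immunity. A haemoglobin list had too few tested members. Marker lists of other cell types were tested in the same way.

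Genes named in the text follow a rule: among genes past the threshold whose libraries separate completely, or between organs move the same way in 4 of 4 mice, the 8 largest rises and falls with mean log2 CPM of at least 4. Gene models without a name were left out, the result of 1 gene is not reported here, and where fewer than 3 genes passed, the 5 of smallest p were considered. Fixed genes of inflammation, fibrosis and macrophage identity, and the members of smallest p of each described list, were added. The groups, tests, lists, markers, this rule and the alternatives below were fixed before the data were examined. Those alternatives were RLE scaling, DESeq2 1.42.0, no filter on low counts, one fit of all 8 sums, a replicate block, each mouse left out, organ from the hashtag ratio, stricter cell filters, hashtag doublets only, equal cell numbers, clustering at resolution 2 and no mouse block. Added after the data had been seen were one Scrublet threshold for all libraries (0.34, the median of the automatic ones), leaving out barcodes with over 10% of UMIs from haemoglobin genes, and a crossed pairing of replicate numbers. The edgeR and camera steps were tested on simulated sums per mouse, drawn with the fitted spread, with 200 genes changed. Hashtag calls, doublet removal, clustering and naming were not simulated, nor were UMIs gathered in single barcodes. The real data may therefore give more false calls and lower recovery than the simulated sums. False calls made up 14 of 159 calls in heart macrophage-like cells and 11 of 111 in heart neutrophil-like cells. They made up 8 of 167 in blood classical monocyte-like cells, 8 of 184 between organs in that class and 8 of 106 for its interaction. In heart macrophage-like and neutrophil-like cells and for the interaction, this was a larger share than the threshold aims at. At 2-fold and 4-fold change respectively, 55% and 90% of changed genes were recovered in heart macrophage-like cells, 24% and 76% in heart neutrophil-like cells, 86% and 90% between organs in classical monocyte-like cells, and 27% and 71% for the interaction in that class.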

Results

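Leukocytes sorted for CD45 and CD11b from blood and heart were profiled in 4 recipient mice transplanted with marrow of a control donor or of a donor that had had a stroke, 2 mice per group. Each mouse gave 1 library in which a hashtag antibody marked the organ. The libraries held 10067873 and 12560452 gene UMIs in control replicates 1 and 2 and 15843922 and 16513840 in stroke replicates 1 and 2, with median UMIs per barcode between 4005 and 4689. After filtering, heart contributed 675, 1405, 1539 and 1292 barcodes and blood 1111, 963, 1368 and 1305, in the order control replicates 1 and 2, stroke replicates 1 and 2. The assignment of barcode suffixes to mice follows the sample numbers in the labels and is assumed in every comparison of donor groups. Control replicate 1 came out male-type, with 1 UMI of Xist and 599 of the Y-linked Ddx3y, while the other 3 mice were female-type, so sex was not balanced between the groups.

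The first question was whether marrow from stroke donors changed which leukocytes were found in heart and blood. Macrophage-like cells made up 40.98% ± 1.14 (SD, n = 2 mice) of heart barcodes with stroke marrow and 31.04% ± 7.64 with control marrow, the largest class in the heart of all 4 mice. Neutrophil-like cells made up 11.02% ± 0.51 against 7.64% ± 1.55, and both stroke mice lay above both control mice for these classes. Dendritic cell-like cells made up 1.97% ± 0.49 against 7.2% ± 3.85 and B cell-like cells 4.0% ± 3.64 against 7.86% ± 1.45, with both stroke mice below both controls. The macrophage-like difference of 9.94 percent points was 4.53 without control replicate 1 and 15.35 without control replicate 2. The dendritic cell-like one of −5.23 was −2.51 and −7.95 without the same mice. The B cell-like one of −3.86 was −1.28 without stroke replicate 1 and −6.43 without stroke replicate 2. Each of these 4 differences had p = 0.333 by an exact two-sided permutation test, which is the smallest that 2 mice against 2 allow. Nonclassical monocyte-like cells (14.02% ± 4.61 against 15.78% ± 0.74), classical monocyte-like cells (6.23% ± 2.47 against 6.01% ± 0.96) and NK cell-like cells (3.31% ± 1.39 against 3.93% ± 0.52) overlapped between the groups. In blood, stroke replicate 2 stood apart: 75.71% of its barcodes were B cell-like (95% Clopper-Pearson interval 73.29 to 78.01), against 6.21% to 10.8% in the other 3 mice, and 3.52% were neutrophil-like, against 22.33% to 38.88%. The sort for CD11b limits which cells could be captured, so shares describe the sorted fraction, and 13.38% to 20.44% of heart barcodes per mouse stayed in unnamed clusters.

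**Figure D1:**
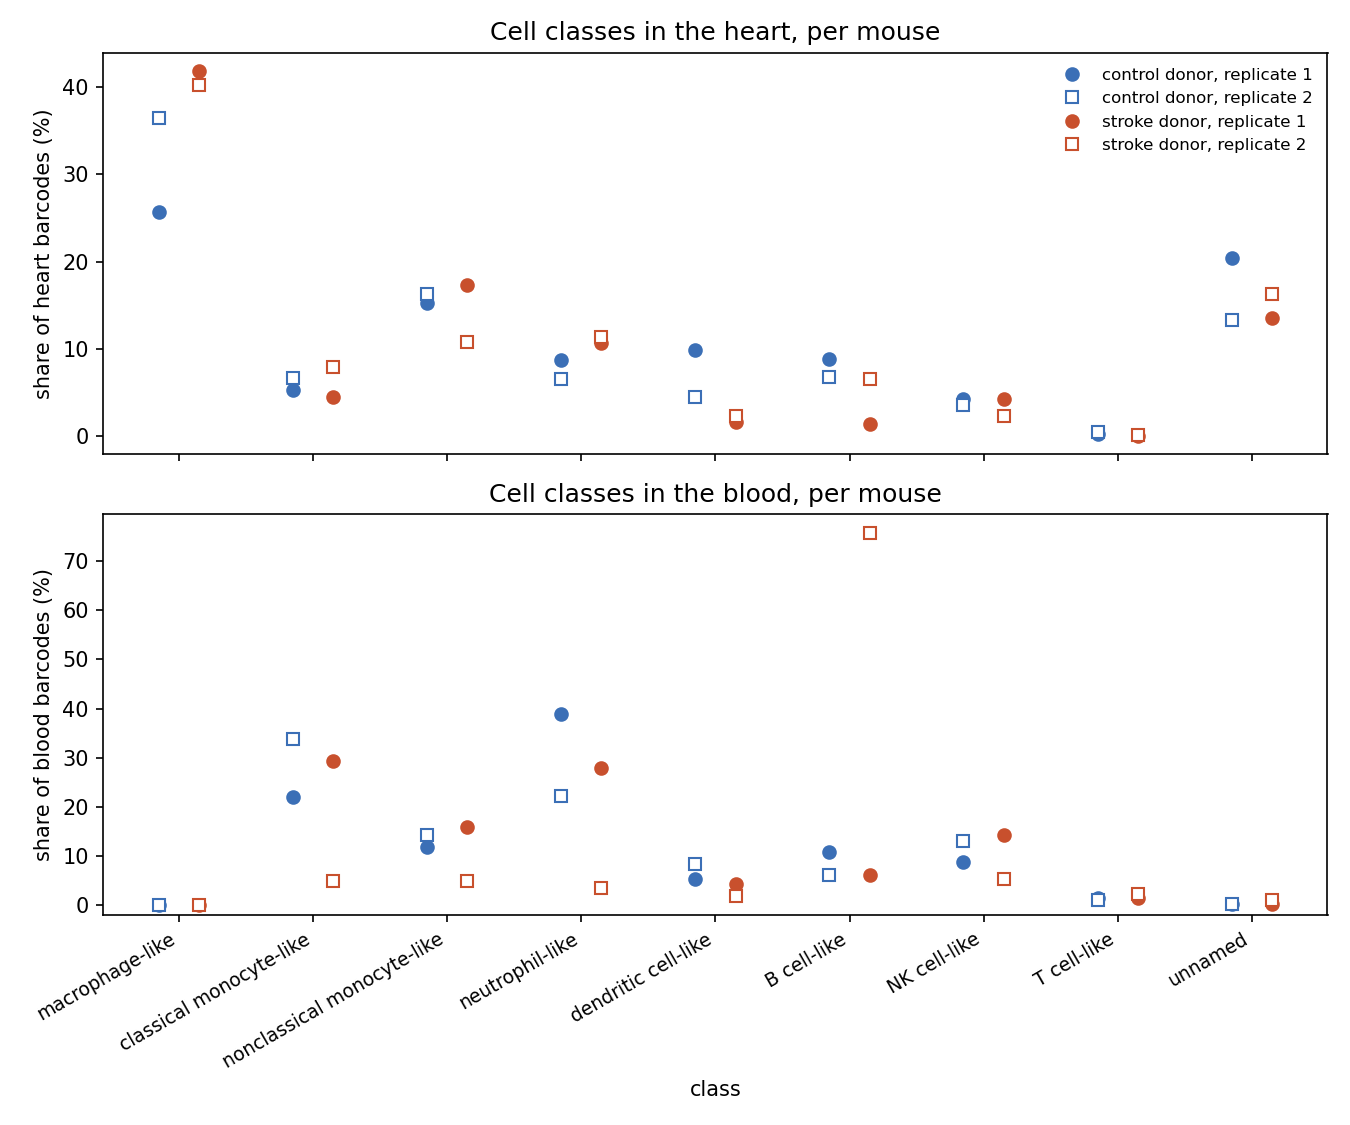
Share of barcodes per cell class (percent of the organ's barcodes, y axis) in heart (top) and blood (bottom), one point per mouse. Blue marks control donors and red stroke donors, circles replicate 1 and squares replicate 2. Heart macrophage-like shares were 25.63% and 36.44% with control marrow and 41.78% and 40.17% with stroke marrow, and the blood of stroke replicate 2 held 75.71% B cell-like barcodes.

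Across all heart cells, transcripts of Il1b and Nlrp3 were higher in both stroke mice than in both controls, but neither passed the transcriptome-wide test, and the groups separated completely in 5136 of the 12479 genes tested (41.2%). Il1b, which encodes the inflammatory cytokine interleukin-1 beta (ENSMUSG00000027398, GRCm38 chromosome 2, 129364570 to 129371139, minus strand), was at 1661 ± 147 CPM (counts scaled to the UMIs of the sum) with stroke marrow and 957.8 ± 105 with control marrow (log2 fold change 0.79, SE 0.16, edgeR adjusted p = 0.553). Nlrp3, the sensor of the inflammasome that activates it, was at 217.7 ± 2.5 against 140.5 ± 9.67 (0.63, SE 0.11, adjusted p = 0.484). Tnf was at 208.2 ± 25.2 against 160.6 ± 8.38 and the neutrophil-attracting chemokine Cxcl2 at 2025 ± 36.0 against 1019 ± 368. The resident macrophage genes Lyve1 (0.56, SE 0.26) and Timd4 (0.64, SE 0.22) had higher values with stroke marrow and the MHC class II genes H2-Aa (−0.39, SE 0.19) and Cd74 (−0.28, SE 0.18) lower ones, with adjusted p = 0.628, 0.565, 0.636 and 0.697. Of the fibrosis genes, Tgfb1 had a log2 fold change of 0.06, Fn1 of −0.17 and Spp1 of 0.10. The latter 2 depended on single mice: Fn1 was at 0.58 without control replicate 1 and −0.91 without stroke replicate 2, and Spp1 at 1.61 without control replicate 1 and −0.71 without control replicate 2.

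As groups, 10 of 12 tested members of the inflammasome and interleukin-1 list were higher with stroke marrow in all heart cells (camera adjusted p = 4.0e-04), and 2 of them passed when adjusted over the list alone. The type I interferon list was higher in 31 of 34 members (3.2e-11), the resident cardiac macrophage list in 18 of 18 (2.2e-10) and the neutrophil marker list in 10 of 10 (7.6e-20). The MHC class II list was lower in 11 of 12 members (1.9e-06) and the marker list of type 2 dendritic cells was lower (3.2e-11). None of these held with an estimated correlation between genes: the adjusted p with an estimated correlation was 0.346, 0.446, 0.408, 0.346, 0.408 and 0.346 in that order. Chemokines and their receptors (2.8e-08, adjusted p = 0.346 with an estimated correlation), matrix remodelling (1.1e-05, 0.346), lysosome and lipid handling (3.4e-07, 0.408), cholesterol synthesis (0.0397, 0.591) and immediate early genes (0.00721, 0.379) were also higher, and cell cycle genes lower (6.3e-08, 0.446). The cholesterol call was lost without control replicate 1, control replicate 2 and stroke replicate 2 (adjusted p = 0.164, 0.0972 and 0.425) and the immediate early call without stroke replicate 1 (0.105). The lists of NF-kB and TNF response, interferon gamma response, glycolysis and HIF-1, oxidative phosphorylation and trained immunity regulators made no call, with camera adjusted p = 0.579, 0.731, 0.984, 0.197 and 0.476. Marker lists of macrophages (3.4e-07) were higher and those of B cells (3.6e-06), T cells (1.9e-10) and mast cells or basophils (4.0e-06) lower in the same test, each also without a call at the estimated correlation. The marker lists thus moved in the same direction as the shares of their classes. Of the other lists called here, inflammasome and interleukin-1, resident macrophage and cell cycle made no call at the preset correlation in any heart class where they were tested. The rest made calls within some classes, for MHC class II in both directions. How far any of these lists followed the shares was not tested.

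Of 12479 genes tested in all heart cells, edgeR called 3, all haemoglobin genes: Hba-a2 (7.13, SE 0.32, adjusted p = 0.00451), Hbb-bs (ENSMUSG00000052305, chromosome 7, 103826534 to 103828096, minus strand; 380.8 ± 49.9 against 2.715 ± 0.245 CPM, adjusted p = 6.6e-04) and Hba-a1 (6.99, SE 0.35, adjusted p = 0.00529). Hba-a1 and Hba-a2 are near-identical copies, so the split of their UMIs is uncertain. A single barcode held 4479 of the 4553 haemoglobin UMIs in the heart of stroke replicate 1 and another held 4987 of 5110 in stroke replicate 2, against 21 and 38 haemoglobin UMIs in the control hearts. With such barcodes left out, edgeR called 0 genes, with 1031 at an unadjusted p under 0.05, and DESeq2 called 48 with them kept. Without control replicate 1, control replicate 2, stroke replicate 1 or stroke replicate 2, edgeR called 20, 36, 4 and 4 genes.

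Heart macrophage-like cells, the class the series title points to through its cardiac inflammation, differed between donor groups in 3 of 10319 genes. S100a9, an alarmin abundant in neutrophils (ENSMUSG00000056071, chromosome 3, 90692632 to 90695721, minus strand), rose from 12.48 ± 2.65 to 59.94 ± 20.5 CPM (log2 fold change 2.35, SE 0.29, adjusted p = 0.0173). Tnip3, an inhibitor of NF-kB signalling that also stood in the type 2 dendritic cell marker list (ENSMUSG00000044162, chromosome 6, 65525313 to 65634040, plus strand), fell from a mean of 138.3 to one of 42.78 (−1.70, SE 0.21, adjusted p = 0.0173). Il31ra, a cytokine receptor subunit (ENSMUSG00000050377, chromosome 13, 112519898 to 112594360, minus strand), fell from 69.38 ± 11.8 to 25.91 ± 3.95 (−1.44, SE 0.19, adjusted p = 0.0269). The Tnip3 UMIs of the controls lay in few barcodes, 170 UMIs in 23 and 316 in 28, with 29.4% and 32.9% of them in a single barcode, against 118 UMIs in 47 and 139 in 41 barcodes of the stroke mice. Its log2 fold change was −0.62 (adjusted p = 1.0) with clustering at resolution 2 and −1.07 (0.7) with organ read from the hashtag ratio. Il31ra kept its size but had adjusted p = 0.1 with the hashtag ratio and 0.181 with stricter cell filters. For S100a9 a single barcode held 45.7% and 70.0% of the UMIs in stroke replicates 1 and 2, and with hashtag doublets alone removed the log2 fold change was 0.15 (adjusted p = 1.0). Without stroke replicate 1 none of the 3 genes passed (adjusted p = 0.0518 each), with 86, 136 and 9 calls without control replicate 1, control replicate 2 and stroke replicate 2.

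Inflammatory genes in this class did not separate beyond the test. Il1b was at 354.9 ± 61.3 CPM against 237.6 ± 21.8 (0.58, SE 0.16, adjusted p = 1.0; it passed without control replicate 1) and Cxcl2 at 1906 ± 103 against 1255 ± 234. Nlrp3 was at 110.8 ± 10.4 against 113.6 ± 15.7 and Tnf at 210.7 ± 10.2 against 215.3 ± 49.6. The recruitment receptor Ccr2 was at 81.16 ± 22.9 against 158.9 ± 101 and Lyve1 at 751.1 ± 65.2 against 720.5 ± 102. By camera, cholesterol synthesis genes were higher in 15 of 17 members (4.7e-05), type I interferon genes in 24 of 33 (4.3e-04) and chemokines and receptors as a list (0.0292), and MHC class II genes were lower in 10 of 11 (0.00265), with adjusted p = 0.526, 0.779, 0.573 and 0.615 with an estimated correlation. The type I interferon call was lost without control replicate 1 (adjusted p = 0.392, with the direction turned) and without stroke replicate 1 (0.386). The MHC class II call was lost without stroke replicate 1 as well (0.386), and the chemokine call without control replicate 2 (0.843) and stroke replicate 2 (0.179). Markers of other cells moved in the same sums: type 2 dendritic cell markers were lower (7.6e-17) and neutrophil and classical monocyte markers higher (5.1e-10 and 8.0e-04), with adjusted p = 0.516, 0.472 and 0.651 with an estimated correlation. The resident macrophage list had a median of 0.06 and made no call (0.379).

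**Figure D2:**
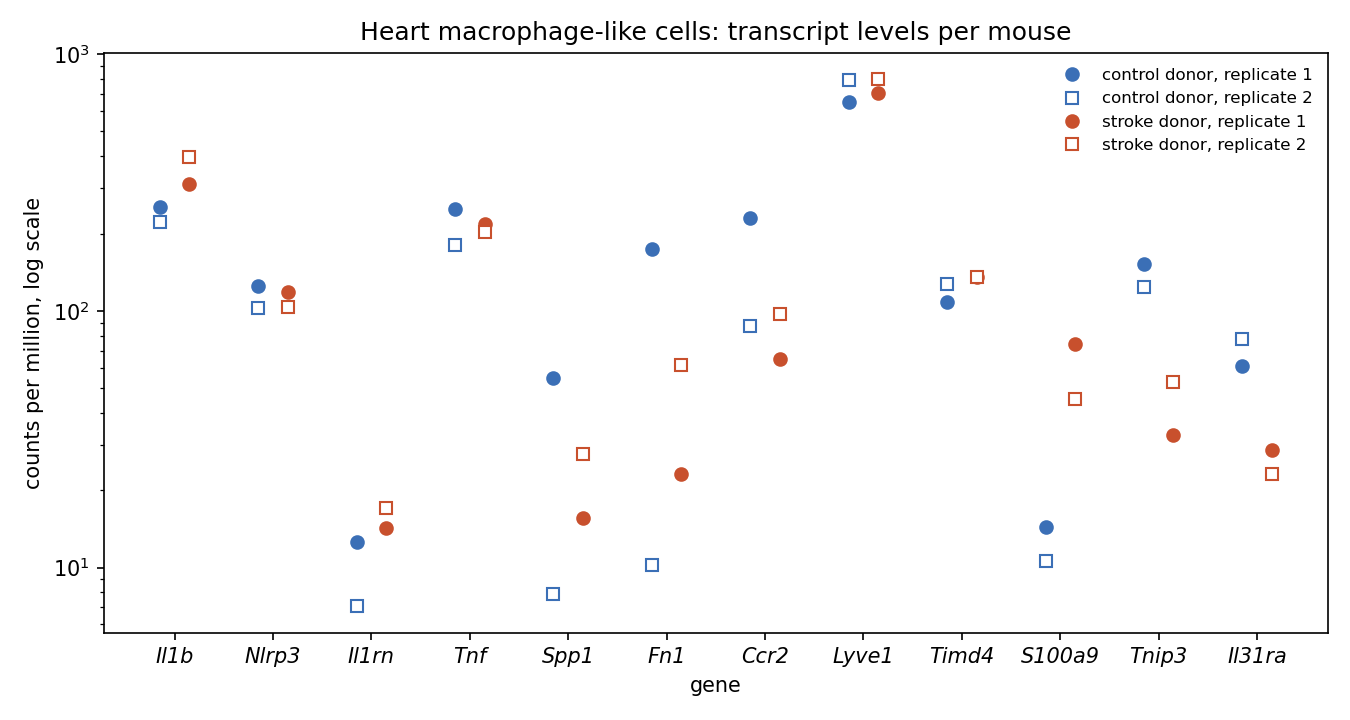
CPM (log axis) of selected genes in heart macrophage-like cells, one point per mouse, control donors in blue beside stroke donors in red. S100a9 averaged 59.94 with stroke marrow and 12.48 with control marrow, Tnip3 42.78 and 138.3, Il31ra 25.91 and 69.38, while Nlrp3 averaged 110.8 and 113.6.

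In the other heart classes, stroke marrow went with scattered calls. In nonclassical monocyte-like cells the interferon-inducible gene Ifi27l2a (ENSMUSG00000079017, chromosome 12, 103442167 to 103443680, minus strand) rose from 303.1 ± 70.9 to 735.2 ± 283 CPM (1.28, SE 0.20, adjusted p = 7.4e-05). Pde7b (1.33) and Chil3 (1.32) rose as well and Fam78b fell (−2.12). DESeq2 called none of these 4 genes (adjusted p = 1.0 each), and stricter cell filters and the single fit of all 8 sums lost all 4 calls, with 0.0555 and 0.14 for Ifi27l2a. Without stroke replicate 1 Ifi27l2a had adjusted p = 0.233 and Fam78b 0.998, and Pde7b had 0.334 without control replicate 1 and 0.0915 without stroke replicate 2. Chil3 had 0.354 without control replicate 2 and 0.32 without stroke replicate 2, and was at 0.63 (adjusted p = 0.998) with hashtag doublets alone removed. The type I interferon list was higher there in 16 of 19 members (9.4e-08, adjusted p = 0.667 with an estimated correlation) and the MHC class II list lower in 7 of 8 (3.1e-08, 0.486). In B cell-like cells the immediate early genes Fos (1.77, adjusted p = 0.00237), Dusp1 (1.62, 0.0471) and Atf3 (1.45, 0.0471) rose with Pgap1 (1.47), and Hmgn2 (−3.22) and Erh (−2.04) fell, although stroke replicate 1 held 22 such cells. DESeq2 called none of these 6 genes, and with clustering at resolution 2 each had adjusted p = 1.0. Without control replicate 2 Dusp1 had adjusted p = 0.524 and Atf3 0.42, and without stroke replicate 2 Dusp1 had 0.194, Hmgn2 0.0629 and Erh 0.474. Without stroke replicate 1 Atf3 had 0.0881 and Pgap1 0.053, and without control replicate 1 Pgap1 had 0.0623. In neutrophil-like cells S100a4 (3.09, adjusted p = 0.0217) and Ahnak (3.11, 0.039) rose, and their log2 fold changes were −0.15 and −0.18 with hashtag doublets alone removed. Both had adjusted p = 0.0592 without control replicate 1.

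In classical monocyte-like cells Ctla2a rose (3.20, adjusted p = 0.041), with 53.2% and 49.1% of its UMIs in a single barcode of each stroke mouse and adjusted p = 0.644 without control replicate 2. In dendritic cell-like cells the cholesterol synthesis gene Fdps rose (1.71, SE 0.32, adjusted p = 0.0458), and Serpina3g (−3.43) and Adam23 (−3.42) fell. DESeq2 called none of these 3 (adjusted p = 0.314, 0.322 and 1.0). Without control replicate 1 Fdps had adjusted p = 0.291 and Serpina3g 0.419, without stroke replicate 1 Fdps had 0.0522, and without stroke replicate 2 the 3 genes had 0.114, 0.114 and 0.104. Adam23 was at −8.71 without stroke replicate 1. The chemokine Ccl5 fell too (−4.79, SE 0.57, adjusted p = 5.3e-04), with 54.8% and 51.9% of its control UMIs in a single barcode per mouse and a log2 fold change of −9.36 without stroke replicate 2. S100a9 (6.04), S100a8 (5.96) and Slpi (5.45) rose in that class, but a single barcode held 100% and 96.9% of the S100a9 UMIs, 109 in stroke replicate 1 and 96 in stroke replicate 2, and Slpi lost its call without either control mouse or stroke replicate 2 and had no test without stroke replicate 1. With organ read from the hashtag ratio S100a9, S100a8 and Slpi were at 1.08, 1.17 and 1.54 (edgeR adjusted p = 0.658, 0.546 and 0.241). Areg, a growth factor gene, had 20 and 15 UMIs in the stroke mice and 0 in both controls, and in each stroke mouse 2 barcodes held them, 1 of these with 19 and 9 UMIs.

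NK cell-like cells of the heart gave the most calls among heart classes, 16 (15 up), and most were macrophage or antigen presentation transcripts. Cd74 had 263 and 215 UMIs with stroke marrow and 3 and 7 with control marrow (5.34, SE 0.36, adjusted p = 4.6e-05), and Apoe 307 and 146 against 1 and 8 (5.32, SE 0.39). The immediate early genes Fos (1.95) and Jun (2.38) also rose, with adjusted p = 0.269 and 0.623 without stroke replicate 1. A single barcode held 62.2% and 65.1% of the Apoe UMIs in the stroke mice, and with 1 doublet threshold for all libraries edgeR called 2 genes and the Apoe log2 fold change was −0.57.

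Over the classes, edgeR called 6 genes in nonclassical monocyte-like cells, 8 in B cell-like, 2 in neutrophil-like, 1 in classical monocyte-like and 8 in dendritic cell-like cells of the heart. Leaving out control replicate 1, control replicate 2, stroke replicate 1 or stroke replicate 2 gave 21, 30, 14 and 11 calls in nonclassical monocyte-like, 22, 23, 16 and 27 in B cell-like and 2, 26, 23 and 28 in neutrophil-like cells. In the same order it gave 5, 2, 21 and 12 in classical monocyte-like, 21, 39, 25 and 17 in dendritic cell-like and 31, 39, 7 and 25 in NK cell-like cells. Of the lists, cholesterol synthesis was higher in classical monocyte-like (0.00621, adjusted p = 0.704 with an estimated correlation), nonclassical monocyte-like (0.0269, 0.667) and dendritic cell-like cells (0.00118, 0.458). The MHC class II list was higher in 5 of 5 members in NK cell-like cells (8.4e-73), the 1 list call between donor groups in the heart, of 36, that held with an estimated correlation (adjusted p = 0.0304). With 1 doublet threshold its members H2-Aa, H2-Eb1 and Cd74 went from 6.13, 5.68 and 5.34 to 1.52, 0.67 and 1.01, and 7 and 3 cells of the stroke mice held 96.2% and 98.2% of the UMIs of 8 macrophage and antigen presentation genes. It was also higher in neutrophil-like cells (5.1e-14, 0.353) and lower in classical monocyte-like (7.3e-04, 0.757) and dendritic cell-like cells (0.0377, 0.615). Without control replicate 1 the cholesterol list had adjusted p = 0.415 in classical monocyte-like and 0.135 in dendritic cell-like cells, and the MHC class II list 0.105 and 0.135 there. Without stroke replicate 2 the MHC class II list had 0.502 and 0.756 in these classes, and in nonclassical monocyte-like cells cholesterol had 0.426, and 0.322 without control replicate 2.

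In blood, stroke marrow went with few differences. Across all blood cells edgeR called 0 of 11575 genes, with 70 at an unadjusted p under 0.05, and DESeq2 called 4. Il1b was at 304 ± 352 CPM with stroke marrow and 447.1 ± 44.6 with control marrow, Nlrp3 at 37.62 ± 43.9 against 77.78 ± 21.7 and Ccr2 at 332.8 ± 346 against 658.9 ± 127. Among the stroke mice, Il1b was at 553.1 CPM in replicate 1 and 54.93 in the B cell-rich replicate 2. Lists of type I interferon (0.00604), chemokines (0.00148), matrix remodelling (5.6e-04), resident macrophage (0.00635), lysosome (1.2e-05), glycolysis (0.00635) and trained immunity genes (0.00923) were lower and cell cycle genes higher (0.0124), each with adjusted p = 0.657 with an estimated correlation, or 0.733 for interferon. Without the B cell-rich stroke replicate 2 the chemokine, resident macrophage and trained immunity calls were lost (0.411, 0.68 and 0.744), and matrix, lysosome and glycolysis genes turned in direction without a call (0.0899, 0.448 and 0.713). Interferon genes were then higher (1.5e-20), and cell cycle genes had 0.177. The resident, interferon and glycolysis calls were lost without control replicate 2 too (0.231, 0.231 and 0.0541), and the cell cycle call without control replicate 1 (0.381) and stroke replicate 1 (0.294). Neutrophil markers were lower (4.5e-05) and B cell markers higher (1.6e-04) in the same sums, by camera at the preset correlation. Without stroke replicate 1 edgeR called 3190 genes, and without stroke replicate 2 it called 10.

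Within blood classes, the antiproliferative gene Btg1 rose in nonclassical monocyte-like cells from 505.5 ± 100 to 944.7 ± 28.7 CPM (0.90, SE 0.16, adjusted p = 0.0236). It kept its call without each mouse in turn and lost it with DESeq2 (0.454), with hashtag doublets alone removed (0.199) and with equal numbers of cells (0.77). The B lineage gene Vpreb3 (−2.26, adjusted p = 0.044) and Chchd10 (−1.63, 0.044) fell in B cell-like cells, but without stroke replicate 2 they were at −1.21 (0.0615) and −1.11 (0.203), and without control replicate 1 Chchd10 had adjusted p = 0.0781. Plac8 rose in NK cell-like cells (2.87, adjusted p = 0.0322), with a log2 fold change of −0.55 under 1 doublet threshold and adjusted p = 0.199, 0.222 and 0.131 without control replicate 1, control replicate 2 and stroke replicate 1. Ltf, a granule gene of immature neutrophils, rose in neutrophil-like cells (116 and 3 UMIs against 0 and 1, adjusted p = 0.00566), with 70.7% and 66.7% of its UMIs in a single barcode of each stroke mouse. It had adjusted p = 0.0593 without control replicate 1 and no test without stroke replicate 1. In classical monocyte-like cells the histone gene Hist1h2ap fell (−4.29, adjusted p = 0.0201), at −2.76 (0.0909) without control replicate 2, −8.71 without stroke replicate 1 and −4.09 (0.999) without stroke replicate 2. Hba-a1 rose (6.32) with 98.0% of the UMIs of stroke replicate 1 in 1 barcode, and was at 2.86 (adjusted p = 0.409) without that mouse. The type I interferon list was higher in neutrophil-like cells in 26 of 27 members (2.8e-09, adjusted p = 0.923 with an estimated correlation) and in nonclassical monocyte-like cells (8.9e-04, 0.867). Immediate early genes (0.0175, 0.867) and NF-kB and TNF response genes (0.0414, 0.867) were also higher in nonclassical monocyte-like cells, and cholesterol synthesis genes in classical monocyte-like cells (0.00431, 0.726). Without control replicate 1 the camera adjusted p was 0.782 for interferon in neutrophil-like cells, and 0.893 for interferon in nonclassical and 0.764 for cholesterol in classical monocyte-like cells, both turned in direction. Without stroke replicate 1 it was 0.572 and 0.711 for the interferon lists, and 0.902 for the NF-kB list, the latter 2 turned. The immediate early call was lost without control replicate 1 (0.276) and stroke replicate 1 (0.501), the NF-kB call also without control replicates 1 (0.165) and 2 (0.0504), and the cholesterol call also without stroke replicate 2 (0.183). EdgeR called 3, 4, 1, 1 and 3 genes in nonclassical monocyte-like, B cell-like, NK cell-like, neutrophil-like and classical monocyte-like cells, and 0 in dendritic cell-like cells, with 99 there at an unadjusted p under 0.05 and 0 by DESeq2. Left-out mice moved these counts to as many as 30, 207, 21, 80, 91 and 272, the highest values coming without stroke replicate 1 for B cell-like, NK cell-like and dendritic cell-like cells and without control replicate 2 for the others.

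Heart was compared with blood within the same mice to ask how leukocytes of the tissue differed from their circulating counterparts. As lists, immediate early and NF-kB target genes were higher in heart by camera in the 6 classes tested in both organs, while T cell-like and mast cell-like cells were too few to test. With an estimated correlation the immediate early list held in dendritic cell-like and B cell-like cells alone (adjusted p = 0.0147 and 0.0224) and the NF-kB list, among classes, in dendritic cell-like cells alone (0.0323). Of all 48 list calls between organs, over all cells and in the classes, 4 held with an estimated correlation and 34 with fry. In classical monocyte-like cells Cxcl2 (ENSMUSG00000058427, chromosome 5, 90903871 to 90905938, plus strand) rose from 2.636 ± 2.53 CPM in blood to 1552 ± 78.5 in heart (log2 fold change 8.71, SE 0.17, adjusted p = 1.9e-21, n = 4 mice). Il1b rose from 65.61 ± 38.4 to 1279 ± 161 (4.24, SE 0.20, adjusted p = 1.6e-14). Egr1 (6.78), Tnf (4.38), Nlrp3 (2.62) and the chemokine Ccl4 (8.87) rose too. Ly6c2 (−0.47), Ccr2 (−0.48), Fn1 (−0.65) and the metabolic regulator Txnip (−1.99) fell. These cells lay mostly in different clusters in the 2 organs, 88.4% in cluster 12 in heart and 95.7% in cluster 2 in blood.

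In nonclassical monocyte-like cells (heart cluster 5, blood cluster 7) Cxcl2 rose by 7.92, Egr1 by 6.55, Il1b by 3.51 and Tnf by 2.90 on the log2 scale, and Ly6c2 (−2.21), Fn1 (−2.09) and Txnip (−2.01) fell. In neutrophil-like cells (heart cluster 9, blood cluster 1) Cxcl2 rose from 11.34 ± 0.45 to 8490 ± 3410 CPM (9.30, SE 0.20), the prostaglandin synthase gene Ptgs2 by 6.18, Il1b by 2.27 and Nlrp3 by 2.09, and Ctla2a fell (−3.28). In dendritic cell-like cells Dusp1 (4.92), Cd14 (4.92) and Egr1 (5.09) rose and Ly6c2 fell (−2.14). In NK cell-like cells Fos (5.47), Nr4a2 (4.72) and Tnfaip3 (4.04) rose. B cell-like cells (heart clusters 8 and 3, blood clusters 3 and 8) had the fewest calls, with Fos rising from 20.58 ± 8.14 to 296.7 ± 226 (3.81, SE 0.22), Junb by 3.16 and Crem by 3.07.

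Of the immediate early and heat shock list, 18 of 19 tested members rose in classical and 18 of 19 in nonclassical monocyte-like cells, 17 of 18 in neutrophil-like, 12 of 18 in dendritic cell-like, 10 of 15 in NK cell-like and 5 of 17 in B cell-like cells. In classical monocyte-like, nonclassical monocyte-like, neutrophil-like and NK cell-like cells the list had adjusted p = 0.064, 0.108, 0.0648 and 0.0811 with an estimated correlation. Of the NF-kB and TNF response list, 22 of 23 rose in classical monocyte-like, 22 of 22 in nonclassical monocyte-like, 17 of 18 in neutrophil-like, 18 of 22 in dendritic cell-like, 7 of 10 in NK cell-like and 3 of 12 in B cell-like cells. Over all cells it held with an estimated correlation (adjusted p = 0.0266). Of 2406 genes tested in all 6 classes, 22 rose in each, among them Atf4, Dusp1, Fos, Ier2, Junb, Nr4a1, Rel and Stat3, 0 fell in each, and 48 rose in one class and fell in another. Type I interferon genes went the other way in classical monocyte-like (26 of 32 lower, 0.0275), dendritic cell-like (16 of 18 lower, 3.0e-04) and nonclassical monocyte-like cells (2.3e-04), with adjusted p = 0.287, 0.301 and 0.177 with an estimated correlation.

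Across all cells the heart fraction was set apart by its macrophages. Lyve1, the hyaluronan receptor of resident macrophages, rose from 0.8513 ± 0.332 to 342.7 ± 103 CPM (8.66, SE 0.21, adjusted p = 2.2e-04). Timd4 rose by 8.61, Gas6 by 8.64 and Cxcl13 by 9.47, and 18 of 18 resident macrophage genes rose (adjusted p = 0.0916 with an estimated correlation). The NK receptor gene Ncr1 fell (−2.38, SE 0.24). Macrophage-like cells were 36.01% ± 7.27 of heart and 0.02% ± 0.04 of blood barcodes and NK cell-like cells 3.62% ± 0.93 and 10.36% ± 4.09, each in the same direction in 4 of 4 mice (p = 0.125 by an exact sign-flip test, the smallest 4 mice allow). EdgeR called 1840 of 12070 genes over all cells (1249 up), 1006 in classical (702 up) and 1026 in nonclassical monocyte-like cells (644 up). It called 879 in neutrophil-like (578 up), 342 in dendritic cell-like (287 up) and 157 in B cell-like cells (92 up), and in NK cell-like cells 216 rose and 86 fell. Leaving out control replicate 1, control replicate 2, stroke replicate 1 or stroke replicate 2 gave 927, 481, 354 and 4805 calls over all cells and 170, 198, 231 and 711 in dendritic cell-like cells. The counts were 151, 55, 65 and 70 in B cell-like, 904, 723, 540 and 624 in neutrophil-like and 197, 221, 173 and 216 in NK cell-like cells.

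**Figure D3:**
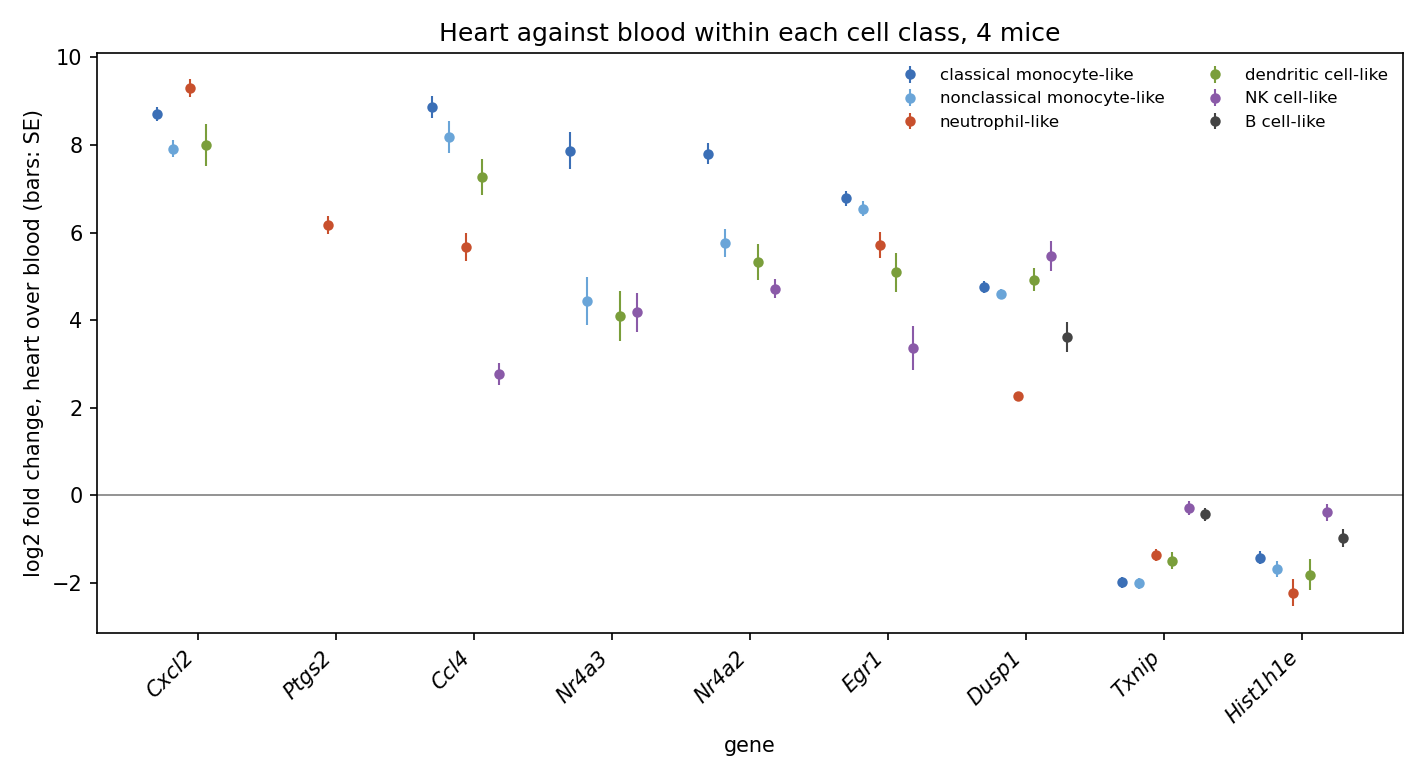
Log2 fold change, heart over blood (y axis), of selected genes (x axis), colored by the class found in both organs, with bars of 1 standard error over 4 mice. Points are left out where a class was not tested or had no UMI in blood. Cxcl2 lies at 8.71 in classical monocyte-like and 9.30 in neutrophil-like cells, and Txnip at −1.99 and −2.01 in classical and nonclassical monocyte-like cells.

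Whether the effect of stroke marrow differed between heart and blood was asked through the interaction of donor and organ. EdgeR called 47 genes in neutrophil-like cells (33 up), 6 in B cell-like cells and 1 in NK cell-like cells. In neutrophil-like cells the granule genes of immature neutrophils Camp (−9.16, SE 0.56, adjusted p = 9.8e-55), Ltf (−7.79) and Ngp (−4.72) had lower heart-over-blood differences with stroke marrow, and Jun (2.01) a higher one. Ribosomal protein genes such as Rpl32 (2.18), Rpl12 (2.73) and Rpl4 (2.85) were also among the rises, with Plac8 (2.69), Igkc (3.02) and Hba-a1 (5.33). In the blood of stroke replicate 1, 3 cells held the 116 Ltf UMIs, with 82 in a single barcode. Both other ways of doublet removal, given below, left far fewer calls in this class. Without stroke replicate 1 Camp was at −3.03 (adjusted p = 1.0), Ltf at −8.63 (0.309), Jun at 9.14 (0.309) and Ngp turned to 1.92 (0.987). Without control replicate 1 they were at −4.16, −3.75, 1.41 (0.279) and −2.05 (0.0681), and Jun had 0.32 without stroke replicate 2. The blood of stroke replicate 2 held 46 neutrophil-like cells, DESeq2 called 0 genes, and edgeR called 17, 82, 0 and 11 without control replicate 1, control replicate 2, stroke replicate 1 and stroke replicate 2. In B cell-like cells Vpreb3 (3.77, adjusted p = 0.0356), Alcam (2.42), Pgap1 (1.78) and the B cell regulator Bach2 (1.26) had higher differences and Dnase1l3 (−3.70) and Rpl13 (−0.46) lower ones, with 6, 27, 48 and 26 calls under the same omissions. Without stroke replicate 2 Vpreb3 was at 0.60 (adjusted p = 0.931) and Dnase1l3 at −2.81 (0.328), and without control replicate 1 Pgap1 had 0.0651, Bach2 0.29 and Rpl13 0.305. DESeq2 called none of the 6. The NK cell-like call was Apoe (4.06, SE 0.53, adjusted p = 2.3e-04), at −1.24 with 1 doublet threshold, with adjusted p = 0.0867 without control replicate 1 and 0.0879 without stroke replicate 2. Over all cells and in classical monocyte-like, nonclassical monocyte-like and dendritic cell-like cells edgeR called 0 genes, with 540, 256, 305 and 288 at an unadjusted p under 0.05 and 1, 0, 0 and 0 by DESeq2. The count over all cells was 3562 without stroke replicate 1 and 71 without stroke replicate 2.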

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

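The tests of doublet removal, of tissue handling, of free fluorescent protein RNA and of the splits of libraries between organs were chosen only after the results had been seen, and the other tests before. A difference between organs in the effect of stroke marrow brought 3 results here: the interaction of donor and organ gave 6 genes in B cell-like cells, 1 in NK cell-like cells and 47 in neutrophil-like cells with edgeR. A signal in data that no comparison used brought the others: transcripts of green fluorescent protein transgenes were present in the kept cells. The first transgene had 1822 UMIs in control replicate 1, 41154 in control replicate 2, 59354 in stroke replicate 1 and 26501 in stroke replicate 2, and the second had 5548 UMIs in control replicate 1 alone. Control replicate 1 thus had UMIs of another mix of transgenes than the other 3 mice.

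Macrophage transcripts were higher in heart NK cell-like cells of stroke donor mice, which also drove the NK cell-like interaction call. Doublets left in by uneven Scrublet thresholds fit this: the median log2 fold change of 8 macrophage and antigen presentation genes went from 5.33 to 0.67 with 1 threshold for all libraries and to 0.80 with hashtag doublets alone removed. The median was 5.34 with organ read from the hashtag ratio and 5.65 with stricter cell filters. All 8 genes were among those called in this comparison, so their starting median was high by selection. With 1 threshold their UMIs went from 34 to 823 in control replicate 2 and from 1251 to 162 in stroke replicate 1. They stayed at 7 in control replicate 1 and 770 in stroke replicate 2. With hashtag doublets alone removed they were 463 and 833 in the controls and still 1251 and 770 in the stroke mice. There the difference shrank through barcodes kept in the controls, not through loss from the stroke mice. Free RNA spread over all cells is ruled out, as 7 of the 66 cells of stroke replicate 1 held 96.2% of these UMIs and 3 of the 30 cells of stroke replicate 2 held 98.2%. The transcripts lay in 4 cells of stroke replicate 1 and 2 of stroke replicate 2 with at least 20 such UMIs, so an effect of stroke marrow on NK cells is not needed for them.

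Immediate early genes were, as a list, higher in heart than in blood in the 6 classes tested, with a rise of 5 of 17 members in B cell-like cells, and the call held with an estimated correlation in dendritic cell-like and B cell-like cells alone (adjusted p = 0.0147 and 0.0224, against 0.064 to 0.108 in the others). Macrophage RNA in other classes could not be settled as a cause, with bounds of 2 and 5: the Fos level was 3.1, 6.5, 30.3 and 11.1 times what the Apoe level would bring along in heart B cell-like cells of control replicates 1 and 2 and stroke replicates 1 and 2, and 87.6, 15.3, 2.6 and 2.2 times in NK cell-like cells. In B cell-like cells Apoe does not mark macrophage RNA alone. In the same order of mice it was at 351.7, 324.1, 354.8 and 120.2 CPM in blood, against 148.8, 161.2, 131.7 and 182.3 in heart. The B cell-like ratios may be too low for this reason. The macrophage gene C1qa was at 5.8, 9.2, 8.8 and 12.8 CPM in heart B cell-like cells. In macrophage-like cells it was at 4517.3, 6939.5, 6462.5 and 6444.5. The former rest on 2, 4, 1 and 5 UMIs, and Fos was not scaled to them. Handling of heart tissue could not be settled either. The lower of the lymphoid medians of the list was 0.42 on the log2 scale, and although this lay under a bound of 0.5 written afterwards, it decides nothing because organ and handling always went together. A response to the tissue and a response to dissociation may both be part of this pattern.

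Fluorescent protein transcripts were lower in heart macrophage-like cells than in heart classical monocyte-like cells, and shallower cells are ruled out as the cause, since the ratio scaled to depth was 5.5, 18.8, 15.4 and 13.5 in control replicates 1 and 2 and stroke replicates 1 and 2. Recipient origin of macrophages without the transcript fits: the resident macrophage list was lower in macrophages with it, by a median of −0.62, in 18 of 18 members (camera adjusted p = 3.0e-24, adjusted p = 0.181 with an estimated correlation). Monocytes sharing a droplet with a macrophage met their bound through control replicate 1 alone. There the dilution estimated from monocyte markers was −0.65, which leaves a difference of 0.03 from the list median over all mice. The dilution was −0.17 in control replicate 2 and −0.51 and −0.49 in stroke replicates 1 and 2, short of that median. Monocyte-derived macrophages with the transcript could carry these markers themselves, so the test cannot decide. Free RNA spread over all cells is ruled out for most of their UMIs, as macrophages with the transcript held 10.7, 15.5, 16.7 and 20.7 times the UMIs of a Poisson spread. For the macrophages with 1 UMI (44 of 70, 55 of 114 and 33 of 73 in the mice other than control replicate 1) free RNA met its bound, but the test cannot decide. The endothelial-like level would give 111.0%, 209.8% and 331.8% of them, and no excess could fail the bound. In stroke replicates 1 and 2 it would give 115.4 and 109.5 such cells, more than the 114 and 73 with any UMI. That level rests on 3, 7 and 3 UMIs in 57, 61 and 23 endothelial-like cells. Donor-derived cells and pairs of cells stay open for the others.

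Other splits of the libraries were counted beside the organ differences. In each of the 7 comparisons 1 of the 8 splits that part every mouse gave as many genes, the real one itself, so the splits are too few for a share under 5%. With the mouse block the real split gave 1840 genes over all cells, 157 in B cell-like, 216 up and 86 down in NK cell-like, 1006 in classical monocyte-like, 342 in dendritic cell-like, 879 in neutrophil-like and 1026 in nonclassical monocyte-like cells, and the highest other split 0 in each. Splits that part fewer mice, fitted without the block, gave at most 4 genes. Every other split mixes heart and blood sums, so differences between organs widen its spread. The low counts of the other splits therefore decide nothing.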

How the results depend on the processing

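Of the log2 fold changes under all settings, 2954 kept direction and side of the threshold, 441 kept direction and lost the call, 144 gained one and 55 turned. These totals pool the named genes of every comparison, between organs as well as donor groups, with the fixed genes in all heart cells and heart macrophage-like cells. A gene that never passed counts as kept while it stays uncalled, so the totals say little about the donor calls alone. Of the list results, 187 kept, 154 lost the call and 9 turned. Counts are given as the reported one followed by the alternative. For every change below the cause was not tested. Depth sets a limit: stroke replicate 1 held 22 B cell-like cells in heart, and genes of low count had no test. Between organs, the calls in classical and nonclassical monocyte-like cells stayed within 725 to 974 and 781 to 939 without each mouse in turn.

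DESeq2 in place of edgeR moved the calls in heart from 3 to 48 over all cells, 8 to 0 in B cell-like and 6 to 0 in nonclassical monocyte-like. Calls in blood went from 0 to 4 over all cells, 4 to 0 in B cell-like, 1 to 0 in NK cell-like, 3 to 0 in classical monocyte-like and 3 to 0 in nonclassical monocyte-like. Calls between organs went from 157 to 90 in B cell-like, 216 up and 86 down to 106 in NK cell-like, 1006 to 519 in classical monocyte-like, 342 to 213 in dendritic cell-like, 879 to 528 in neutrophil-like and 1026 to 457 in nonclassical monocyte-like. Calls for the interaction went from 0 to 1 over all cells, 6 to 0 in B cell-like and 47 to 0 in neutrophil-like. The sign turned for Ly6c2 0.11 to −0.25 (heart, macrophage-like).

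RLE scaling moved the calls in heart from 2 to 6 in neutrophil-like. The count for the interaction went from 6 to 3 in B cell-like.

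Testing without a low-count filter moved the calls in heart from 3 to 659 over all cells, 8 to 27 in B cell-like, 16 to 54 in NK cell-like, 1 to 14 in classical monocyte-like, 8 to 73 in dendritic cell-like, 3 to 63 in macrophage-like, 2 to 91 in neutrophil-like and 6 to 14 in nonclassical monocyte-like. Calls in blood went from 0 to 4 over all cells, 4 to 99 in B cell-like, 1 to 29 in NK cell-like, 3 to 36 in classical monocyte-like, 0 to 33 in dendritic cell-like, 1 to 10 in neutrophil-like and 3 to 14 in nonclassical monocyte-like. Calls between organs went from 157 to 277 in B cell-like and 342 to 684 in dendritic cell-like. Calls for the interaction went from 6 to 38 in B cell-like, 1 to 7 in NK cell-like, 0 to 3 in classical monocyte-like, 0 to 14 in dendritic cell-like and 47 to 21 in neutrophil-like. Signs turned for Tnf −0.01 to 0.01 and Nlrp3 −0.01 to 0.00 (heart, macrophage-like).

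A single fit of all 8 sums moved the calls in heart from 8 to 2 in B cell-like, 8 to 1 in dendritic cell-like, 2 to 16 in neutrophil-like and 6 to 0 in nonclassical monocyte-like. The count in blood went from 0 to 4 over all cells, 4 to 0 in B cell-like, 1 to 3 in NK cell-like, 3 to 1 in classical monocyte-like, 1 to 0 in neutrophil-like and 3 to 1 in nonclassical monocyte-like.

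Organ read from the hashtag ratio moved the calls in heart from 8 to 5 in B cell-like, 8 to 13 in dendritic cell-like, 3 to 0 in macrophage-like, 2 to 0 in neutrophil-like and 6 to 2 in nonclassical monocyte-like. The count in blood went from 4 to 0 in B cell-like, 3 to 1 in classical monocyte-like and 1 to 0 in neutrophil-like. The count for the interaction went from 6 to 3 in B cell-like, 0 to 2 in classical monocyte-like and 47 to 5 in neutrophil-like. Here the log2 fold change turned for Spp1 0.10 to −0.16 (heart, all cells), Tnf −0.01 to 0.05 and Nlrp3 −0.01 to 0.07 (heart, macrophage-like).

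Stricter cell filters moved the calls in heart from 8 to 0 in B cell-like, 1 to 0 in classical monocyte-like, 8 to 34 in dendritic cell-like, 2 to 0 in neutrophil-like and 6 to 0 in nonclassical monocyte-like. Calls in blood went from 1 to 3 in NK cell-like and 3 to 10 in nonclassical monocyte-like. Calls for the interaction went from 6 to 0 in B cell-like, 0 to 1 in classical monocyte-like, 47 to 10 in neutrophil-like and 0 to 1 in nonclassical monocyte-like. The log2 fold change turned for Nlrp3 −0.01 to 0.01 (heart, macrophage-like). The share difference of classical monocyte-like cells in heart went from 0.22 to −0.09 percent points.

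Removal of hashtag doublets alone moved the calls in heart from 8 to 4 in B cell-like, 16 to 1 in NK cell-like, 8 to 21 in dendritic cell-like, 3 to 1 in macrophage-like and 2 to 0 in neutrophil-like. Those in blood went from 4 to 0 in B cell-like, 1 to 0 in NK cell-like and 3 to 0 in nonclassical monocyte-like. Those for the interaction went from 1 to 2 in NK cell-like, 0 to 2 in dendritic cell-like and 47 to 3 in neutrophil-like. Turned log2 fold changes were Apoe 5.32 to −0.25 (heart, NK cell-like), Spp1 −0.29 to 0.01 and Isg15 0.07 to −0.17 (heart, macrophage-like), S100a4 3.09 to −0.15, Ahnak 3.11 to −0.18, Rpl32 1.76 to −0.38 and Plac8 2.40 to −0.51 (heart, neutrophil-like), Lyz2 3.33 to −1.54 (blood, NK cell-like), Apoe 4.06 to −1.01 (interaction, NK cell-like).

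A common Scrublet threshold moved the calls in heart from 8 to 1 in B cell-like, 16 to 2 in NK cell-like, 8 to 21 in dendritic cell-like, 2 to 0 in neutrophil-like and 6 to 3 in nonclassical monocyte-like. Those in blood went from 4 to 71 in B cell-like, 1 to 0 in NK cell-like and 3 to 1 in classical monocyte-like. Those for the interaction went from 6 to 60 in B cell-like, 0 to 1 in dendritic cell-like and 47 to 4 in neutrophil-like. Genes that turned were Apoe 5.32 to −0.57 (heart, NK cell-like), Ly6c2 0.11 to −0.17 (heart, macrophage-like), Rpl32 1.76 to −0.01 (heart, neutrophil-like), Plac8 2.87 to −0.55 and Lyz2 3.33 to −1.59 (blood, NK cell-like), Apoe 4.06 to −1.24 (interaction, NK cell-like).

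Omission of haemoglobin-rich barcodes moved the calls in heart from 3 to 0 over all cells and 2 to 6 in neutrophil-like. A turned log2 fold change was Hba-a1 5.33 to −1.64 (interaction, neutrophil-like).

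Equal cell numbers per mouse moved the calls in heart from 3 to 0 over all cells, 8 to 1 in B cell-like, 16 to 0 in NK cell-like, 1 to 0 in classical monocyte-like, 8 to 2 in dendritic cell-like, 3 to 0 in macrophage-like, 2 to 0 in neutrophil-like and 6 to 2 in nonclassical monocyte-like. Those in blood went from 4 to 0 in B cell-like, 1 to 9 in NK cell-like, 3 to 0 in classical monocyte-like, 1 to 0 in neutrophil-like and 3 to 0 in nonclassical monocyte-like. Among genes, signs turned for Il1rn 0.78 to −0.08, Nlrp3 −0.01 to 0.09, Ly6c2 0.11 to −0.81 and Lyve1 0.06 to −0.05 (heart, macrophage-like).

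Clustering at resolution 2 moved the calls in heart from 8 to 0 in B cell-like, 1 to 2 in classical monocyte-like, 8 to 43 in dendritic cell-like and 2 to 0 in neutrophil-like. Those in blood went from 3 to 9 in classical monocyte-like. Log2 fold changes turned for Nlrp3 −0.01 to 0.01, Fn1 −0.93 to 1.68 and Spp1 −0.29 to 1.34 (heart, macrophage-like).

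An estimated correlation in place of the preset one moved the list calls in heart from 10 to 0 over all cells, 4 to 0 in B cell-like, 3 to 1 in NK cell-like, 2 to 0 in classical monocyte-like, 7 to 0 in dendritic cell-like, 4 to 0 in macrophage-like, 3 to 0 in neutrophil-like and 3 to 0 in nonclassical monocyte-like. An estimated correlation in place of the preset one moved the list calls in blood from 8 to 0 over all cells, 1 to 0 in classical monocyte-like, 1 to 0 in neutrophil-like and 4 to 0 in nonclassical monocyte-like. Fry in place of camera moved those in heart from 10 to 0 over all cells, 4 to 0 in B cell-like, 2 to 0 in classical monocyte-like, 7 to 0 in dendritic cell-like, 4 to 0 in macrophage-like, 3 to 0 in neutrophil-like and 3 to 0 in nonclassical monocyte-like. Fry in place of camera moved those in blood from 8 to 0 over all cells, 1 to 0 in classical monocyte-like, 1 to 0 in neutrophil-like and 4 to 0 in nonclassical monocyte-like.

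Each mouse was also left out in turn, which leaves an arm with 1 mouse that is assumed to vary like the others. Calls in heart then ranged from 4 to 36 over all cells, 16 to 27 in B cell-like, 7 to 39 in NK cell-like, 2 to 21 in classical monocyte-like, 17 to 39 in dendritic cell-like, 0 to 136 in macrophage-like, 2 to 28 in neutrophil-like and 11 to 30 in nonclassical monocyte-like. Calls in blood then ranged from 0 to 3190 over all cells, 27 to 207 in B cell-like, 2 to 21 in NK cell-like, 4 to 91 in classical monocyte-like, 1 to 272 in dendritic cell-like, 0 to 80 in neutrophil-like and 7 to 30 in nonclassical monocyte-like. Calls between organs then ranged from 354 to 4805 over all cells, 55 to 151 in B cell-like, 173 to 221 in NK cell-like, 170 to 711 in dendritic cell-like and 540 to 904 in neutrophil-like. Calls for the interaction then ranged from 0 to 3562 over all cells, 6 to 48 in B cell-like, 0 to 5 in NK cell-like, 0 to 3 in classical monocyte-like, 0 to 116 in dendritic cell-like, 0 to 82 in neutrophil-like and 0 to 7 in nonclassical monocyte-like. For heart, all cells, log2 fold changes turned in Mmp9 −0.02 to 0.62, Fn1 −0.91 to 0.58, Spp1 −0.71 to 1.61, Ccl2 −0.63 to 0.47 and Ccr2 −0.75 to 0.06. For heart, macrophage-like, log2 fold changes turned in Tnf −0.24 to 0.23, Nlrp3 −0.16 to 0.12, Fn1 −2.09 to 2.01, Spp1 −1.37 to 1.42, Ccl2 −1.20 to 0.20, Ly6c2 −1.25 to 4.31, Lyve1 −0.08 to 0.21, Isg15 −0.06 to 0.21 and Irf7 −0.17 to 0.65. For interaction, neutrophil-like, log2 fold changes turned in Igkc −0.34 to 3.58 and Ngp −5.81 to 1.92. List calls in heart ranged from 2 to 5 in B cell-like, 4 to 6 in NK cell-like, 1 to 6 in classical monocyte-like, 2 to 9 in dendritic cell-like, 3 to 8 in macrophage-like and 2 to 5 in nonclassical monocyte-like. List calls in blood ranged from 2 to 11 over all cells, 0 to 3 in B cell-like, 0 to 2 in NK cell-like, 2 to 5 in classical monocyte-like, 0 to 4 in dendritic cell-like, 0 to 6 in neutrophil-like and 1 to 5 in nonclassical monocyte-like. The camera adjusted p of lists that turned ranged as follows: type I interferon response 1.9e-10 to 0.392 (heart, macrophage-like), type I interferon response 1.5e-20 to 0.231 (blood, all cells), matrix remodelling and fibrosis 5.3e-09 to 0.0899 (blood, all cells), lysosome, lipid and phagocytosis 1.1e-11 to 0.448 (blood, all cells), glycolysis and HIF-1 2.8e-04 to 0.713 (blood, all cells), cholesterol synthesis 7.9e-10 to 0.764 (blood, classical monocyte-like), NF-kB and TNF response 2.3e-04 to 0.902 (blood, nonclassical monocyte-like) and type I interferon response 3.6e-11 to 0.893 (blood, nonclassical monocyte-like). Share differences in heart turned, with ranges in percent points of −1.61 to 0.36 for NK cell-like, −1.53 to 1.96 for classical monocyte-like, −1.19 to 2.72 for endothelial-like, −0.34 to 0.01 for fibroblast-like and −5.02 to 1.5 for nonclassical monocyte-like cells. Share differences in blood turned, with ranges in percent points of −2.30 to 67.19 for B cell-like, −5.54 to 3.35 for NK cell-like, −22.95 to 1.53 for classical monocyte-like and −8.16 to 2.87 for nonclassical monocyte-like cells.

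The mice of a number in the 2 groups share only that number, and a replicate block was tried. With the replicate block the calls in heart went from 8 to 0 in B cell-like, 1 to 2 in classical monocyte-like, 8 to 21 in dendritic cell-like and 2 to 84 in neutrophil-like. With the replicate block the calls in blood went from 4 to 0 in B cell-like, 1 to 13 in NK cell-like, 3 to 26 in classical monocyte-like, 1 to 11 in neutrophil-like and 3 to 8 in nonclassical monocyte-like. List calls with that block in blood went from 0 to 2 in B cell-like, 0 to 1 in NK cell-like, 0 to 1 in dendritic cell-like and 1 to 2 in neutrophil-like cells. The correlation of mice sharing a number was −0.34 over all heart cells, −0.25 over all blood cells and −0.30 in blood dendritic cell-like cells, and a crossed pairing gave there 156, 0 and 1 calls. In the other comparisons the correlation lay between −0.05 and 0.14, the latter in heart neutrophil-like cells. Crossed pairing gave from 0 calls, as in heart neutrophil-like cells, to 19 in blood classical monocyte-like cells there.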

Other observations

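Within heart macrophage-like cells, those with a fluorescent protein UMI were compared with those without in the same 4 mice, outside the comparisons of the report. Of 7548 genes tested, edgeR called 499, with 336 higher in cells with the transcript. Monocyte genes led the rises: Plac8 had a log2 fold change of 5.38, Hp of 4.57, Chil3 of 4.42 and Ccr2 of 2.30 (adjusted p = 1.6e-08). Genes of resident macrophages fell: Folr2 by −0.82 (adjusted p = 1.7e-04), Timd4 by −0.67, Lyve1 by −0.64, Cd163 by −0.60 and Mrc1 by −0.40. The list of classical monocyte markers was higher (2.2e-53, adjusted p = 0.0301 with an estimated correlation). Cells with the transcript were also deeper, with medians of 8790 against 5172, 5414.5 against 4547.5, 6868.5 against 4833 and 6077 against 4515 UMIs in control replicates 1 and 2 and stroke replicates 1 and 2. Cluster 4, led by Lyve1, Folr2 and Timd4, held 13.2%, 34.3%, 25.4% and 28.8% of those with it and 45.2%, 43.4%, 43.9% and 39.7% of those without, so the comparison is also one between clusters. After thinning to equal depth, 12.8%, 6.6%, 9.6% and 8.3% of heart macrophage-like cells held a UMI of it in control replicates 1 and 2 and stroke replicates 1 and 2, against 71.4%, 84.4%, 95.6% and 95.2% of heart classical monocyte-like cells. Many of these cells held a single UMI, 9 of 38, 44 of 70, 55 of 114 and 33 of 73 macrophage-like cells before thinning, and 94.8% to 97.2% of the UMIs lay in cells with at least 5. For comparison, heart B cell-like cells held a UMI in 1.3%, 4.7%, 20.5% and 3.4% of cells after thinning, and blood B cell-like cells in 7.7%, 15.5%, 19.5% and 4.4%. In the heart of stroke replicate 1, 6 of 22 B cell-like cells held 82 UMIs before thinning. Whether B cell-like cells carry the transgene themselves was not tested, so their shares set no background level. As background, endothelial-like cells held a UMI in 2.5%, 3.9% and 5.7% of cells after thinning, without control replicate 1.

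Of 59 calls between donor groups, a single barcode held most of a mouse's UMIs in at least 1 mouse of the higher group for 25 and in both mice of that group for 17. With the labels of the mice split otherwise, the highest count exceeded the real one in heart classical monocyte-like cells (3 against 1) and in blood B cell-like cells (6 against 4). The counts tied at 0 over all blood cells and in blood dendritic cell-like cells, and elsewhere the real one was the highest. With 2 mice against 2, chance alone puts the real split first 1 time in 3, so this decides nothing.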
